A study of Rattus norvegicus with 20 samples.

How the data were processed

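Total RNA of pancreatic islets was hybridised to Affymetrix Rat Gene 1.0 ST arrays, 1 array per animal, and the table used here holds 1 column per array. Its values are on a log2 scale and, per the labels and the design text deposited with them, were normalised by the authors with the robust multi-array average (RMA), a method that corrects background, equalises the arrays and summarises probes into probe sets. The submitters' processing notes name only MAS5, a different method, and this conflict was not resolved. The log2 values as deposited ran from 1.18 to 14.17, the array medians from 6.3 to 6.5, and sorted columns differed by up to 0.38, so the arrays were close to a common distribution without sharing it exactly. No filter on dim probe sets is given in the sources used here. The values of 198 probe sets repeat those of an earlier probe set.

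Probe sets were named through the platform annotation, of which 15310 had exactly 1 gene symbol. By gene number 15279 of these matched the RefSeq genes of the GRCr8 assembly, used for names alone, and 0 symbols changed. Probe sets with several symbols (323) were named after none of them, and 13581 were unnamed here. No coordinates were used.

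Groups came from the labelled sex and paternal diet of each sample, with replicates numbered in accession order, which names an array and pairs none. Each array was taken as a separate animal. The design text gives the litters as the units of replication, and the number of fathers is below the number of arrays, so animals that shared a father could not be modelled.

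Tests were run on the values as deposited with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparison across both sexes, the interaction and the comparison between the sexes used all 20 arrays with 4 group means, as in the analysis by sex and diet that the series describes. The comparisons within a sex used the 10 arrays of that sex. The series applied an unadjusted threshold of 0.05, so counts at that threshold are given as well. All tests were two-sided.

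The gene lists, 28 in number with 580 members, were fixed before the data were examined and cover islet cell types, other cells an islet preparation could hold, immune and inflammatory genes, stress, metabolism, cell cycle, blood and sex. Each gene was represented by its probe set with the highest mean. Lists were tested with camera at a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over the 28 lists, and beside it with an estimated correlation, with fry and with an exact permutation of the list mean per array (252 splits within a sex, 63504 over both sexes). Within a sex the smallest two-sided p that this permutation allows is 0.00794, so a single list could not pass after adjustment over 28 lists, and a permutation count of 0 there says little. Lists that no comparison called were alpha, delta and PP cell markers, Schwann cell markers, neutrophil and mast cell markers, ER stress genes, apoptosis genes and sex hormone, prolactin and growth hormone signalling genes; across both sexes their mean diet differences were -0.08, -0.04, 0.02, 0.04, 0.05 and 0.01.

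The rule for named genes, also fixed before the data were examined, took for each diet comparison the 10 largest increases and the 10 largest decreases among single-symbol probe sets past the adjusted threshold or, with fewer than 10 such probe sets, past the unadjusted one. It took 5 and 5 for the interaction, 6 and 6 for the comparison of the sexes, and the 4 members of each called list with the largest change in its direction. Islet hormone, glucose transporter, immune and cytokine genes (Ins1, Ins2, Iapp, Gcg, Sst, Slc2a2, Il13ra2, Il1b, Tnf, Ccl2, Cd68, Cd3e) were always taken. Pdx1 and Mafa had no single-symbol probe set and were not used here.

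The limma fits for diet and for the interaction were tested on simulated data with the real means and spreads, in which 100 probe sets were changed by 0.5 log2 and 100 by 1 log2. Of those of 0.5 and 1 respectively, limma recovered 74% and 99% across both sexes, 33% and 94% in females, 17% and 84% in males, and 13% and 61% in the interaction. The simulation drew probe sets independently, so it says nothing about correlated genes. Camera at its preset correlation was tried on similar data, and the exact permutation on random scores. The comparison between the sexes and the other tests were not simulated.

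Marker lists of small intestine, brown fat and lymph node structure were written after a first look at the arrays. Each was divided into genes seen in that look and genes not yet inspected, and the median excesses given here come from the latter unless stated. Ucp1 was the single brown fat gene seen beforehand. Of the uninspected genes measured, 7 of 13 intestine, 4 of 14 brown fat and 2 of 10 lymph node markers lay above the typical array median in the other arrays, and 1 lymph node marker was also in the macrophage list. Bcl6 and Fcrla, 2 lymph node markers, are B cell genes, so the relation with the B cell list was also computed without them. Marco, the marker shared with the macrophage list, was left out there too, which left 7 genes.

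Alternatives covered a filter on dim probe sets, single-symbol probe sets alone, other variance models, array weights, quantile normalization, an acinar marker score as covariate, a threshold of 0.1, all arrays in a single fit, a model without interaction, other list tests, the mean over probe sets of a gene, and leaving out each array in turn. Leaving out both least correlated arrays, and for Reg3a also female HFD-sired 5, was one of several fits added after the data had been seen. Figures were drawn with matplotlib 3.10.9.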

Results

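Islet transcriptomes were measured in 20 Sprague Dawley rats, an outbred laboratory strain, killed unfasted at 4 to 5 weeks of age. Their fathers had eaten a high-fat diet (HFD) or a control diet for 12 weeks before mating, and the mothers ate chow. The series asked whether a father's HFD changes gene expression in the pancreatic islets of the offspring, inflammation genes included, and whether daughters and sons differ in this. The arrays formed 4 groups of 5: females and males sired by control fathers, and females and males sired by HFD fathers. Each array gave log2 values for 29214 probe sets. A single gene symbol was attached to 15310 of them (14506 genes), 323 had several and 13581 were unnamed here. Array medians lay between 6.3 and 6.5. Arrays have no read depth, so their number limits the precision: the median standard error (SE) of a diet difference was 0.09 log2 over both sexes, 0.11 in females and 0.13 in males. Litters came from 8 control and 9 HFD fathers while each diet had 10 arrays, so some arrays shared a father, although per the series design text each array stood for a litter. Which ones is not given, and all p-values treat the arrays as independent.

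Hormone transcripts marked all 4 groups as islet tissue. Ins2 averaged 14.01 ± 0.04 (SD, n = 5) in control-sired females and 13.98 ± 0.03 in HFD-sired males, and Gcg, the glucagon gene, averaged between 13.76 and 13.86 in the groups. Such values are close to the highest in the whole table (14.17), where a difference between arrays is hard to see. Transcripts of pancreatic acinar cells, which make digestive enzymes, were also abundant, with list means of 12.41 ± 0.39 (SD, n = 10) in HFD-sired and 12.52 ± 0.33 in control-sired animals.

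Transcripts of other tissues were high in a few arrays. In female HFD-sired 1, 13 small intestine markers lay a median of 2.79 log2 above the other arrays: Slc6a19, an intestinal amino acid transporter, read 9.43 there against a median of 5.37 in 18 other arrays, and the enzyme gene Mep1a read 7.91 against 3.43. Brown fat markers had a median excess of 0.74 over 14 genes in the same array, the lipid droplet gene Cidec reading 8.05 against 5.62. Of the 14 genes 7 were more than 1 higher, Adipoq (7.88 against 5.24) and Gpd1 (10.28 against 6.51) among them. Others were little raised or lower, such as Dio2 (4.76 against 4.56), Elovl3 (4.27 against 4.43) and Kcnk3 (7.03 against 7.32). Ucp1, the thermogenic uncoupling protein gene, was seen before these markers were chosen. It read 10.18 there and also 8.12 in female control-sired 1, against 4.84, and was 1.54 above the others in female HFD-sired 4. Over the 14 genes not seen before, female control-sired 1 had a median excess of 0.08, with 2 genes, Adipoq and Gpd1, more than 1 above the others. Male control-sired 1 had a small intestine excess of 0.83 and female HFD-sired 5 of 0.28, and 12 intestine genes seen beforehand lay a median of 2.13 and 1.40 higher in these 2 arrays. Markers of lymph node structure were raised in several arrays of all groups, by 1.45 in female HFD-sired 1, 0.83 in female control-sired 1, 0.86 in male control-sired 3, 0.85 in male HFD-sired 3, 0.51 in male control-sired 1, 0.50 in male HFD-sired 1 and 0.41 in female HFD-sired 3. The median correlation with the other arrays was 0.941 for female HFD-sired 1 and 0.963 for male control-sired 1, against 0.977 to 0.990 for the others.

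**Figure D1:**
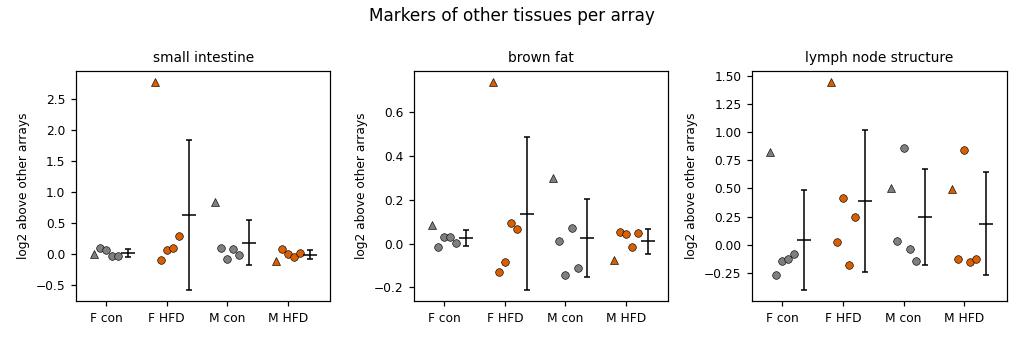
Median excess (log2) of small intestine, brown fat and lymph node structure markers in each array over the other arrays, for females (F) and males (M) sired by control (con) or HFD fathers; points are arrays, the triangle is replicate 1, and bars are mean ± SD of 5 arrays. Female HFD-sired 1 is the highest array in all 3 panels, at 2.79, 0.74 and 1.45.

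Across both sexes, the largest differences by paternal diet among single-symbol probe sets with an unadjusted p under 0.05 were in the regenerating islet-derived genes Reg3a and Reg3b, which encode secreted lectins of the exocrine pancreas and gut. Reg3a was lower in the HFD-sired offspring by a log2 difference of -2.24 ± 0.73 (SE, 10 arrays against 10) and Reg3b by -2.18 ± 0.80, and neither passed the test (adjusted p = 0.962 for both). Control-sired arrays lay between 10.05 and 12.86 for Reg3a, while HFD-sired arrays spread from 6.01 to 12.16, with 6 of 10 below every control. Adora1, the adenosine A1 receptor gene, differed by -0.52 ± 0.10, with 8 of 10 HFD-sired arrays below every control (adjusted p = 0.962). Other large decreases were in A1bg (-0.57 ± 0.23), the intelectin gene Itln1 (-0.50 ± 0.17), Sardh (-0.48 ± 0.23), Ugt2b37 (-0.44 ± 0.13), Itih4 (-0.43 ± 0.11) and Hba-a3, a globin gene (-0.41 ± 0.19). Large increases were in Klkb1, the plasma prekallikrein gene (0.57 ± 0.21), the phosphatase gene Dusp1 (0.55 ± 0.26), Gucy2c (0.53 ± 0.25), Plk2 (0.49 ± 0.22), Ppp1r15a (0.43 ± 0.19), Ephx2 (0.38 ± 0.14) and the clock gene Per1 (0.38 ± 0.17).

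**Figure D2:**
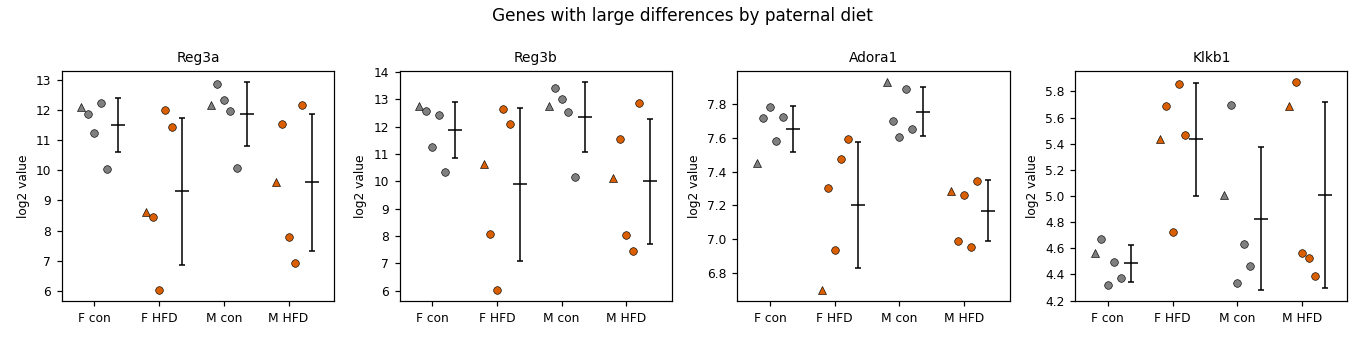
Log2 values of Reg3a, Reg3b, Adora1 and Klkb1 in each array, for females (F) and males (M) sired by control (con) or HFD fathers; points are arrays, the triangle is replicate 1, and bars are mean ± SD of 5 arrays. HFD-sired arrays spread from 6.01 to 12.16 for Reg3a, and control-sired arrays from 10.05 to 12.86.

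The genes of the islet hormones read near the top of the scale, where small differences say little: the log2 difference was -0.04 ± 0.04 for Ins1, -0.02 ± 0.04 for Ins2, -0.06 ± 0.12 for the amylin gene Iapp, -0.05 ± 0.08 for Gcg and -0.05 ± 0.12 for the glucose transporter gene Slc2a2. Inflammation genes had wider errors: 0.10 ± 0.20 for Il1b, -0.03 ± 0.14 for Tnf, 0.05 ± 0.36 for the chemokine gene Ccl2, 0.21 ± 0.27 for the macrophage gene Cd68 and 0.49 ± 0.59 for Il13ra2, a decoy receptor of interleukin 13. With limma, 0 of 29214 probe sets passed an adjusted p of 0.05, and 1151 had an unadjusted p under 0.05 (322 higher, 829 lower), against 1460.7 expected by chance. Ordinary least squares without moderation also gave 0, with 1168 at the unadjusted threshold. In simulated arrays with these spreads, 74% of probe sets changed by 0.5 log2 and 99% of those changed by 1 were recovered. Those arrays held 100 changed probe sets of each size and drew all probe sets independently. The rates therefore do not show that such changes would have passed among the real, correlated probe sets. Adora1, at -0.52 ± 0.10, did not pass. Without female HFD-sired 1 and male control-sired 1, the count of adjusted calls was 0 and that of unadjusted ones 1142.

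Of 28 gene lists, 13 shifted with paternal diet across both sexes in camera with its preset correlation, 10 up and 3 down, and none of these calls held with an estimated correlation. Immediate early and heat shock genes, which respond within minutes to stimulation or stress, rose by a mean of 0.30 log2, with all 18 measured members above 0 (adjusted p = 0.756 with an estimated correlation); Fos was at 0.83 ± 0.43, Egr1 at 0.64 ± 0.37 and Jun at 0.64 ± 0.32. Blood markers fell by 0.18, with all 8 members below 0, among them the globin gene Hbb-b1 at -0.41 ± 0.23. Cell cycle genes rose by 0.10 (26 of 28 above 0; Pcna 0.25 ± 0.12) and cholesterol and fatty acid synthesis genes by 0.08 (16 of 17; Idi1 0.30 ± 0.12). Oxidative phosphorylation genes rose by 0.10 (29 of 31; Cycs 0.32 ± 0.17), fatty acid oxidation genes by 0.11 and glycolysis genes by 0.06. T and NK cell markers rose by 0.18, mesenchyme genes by 0.11, endothelial markers by 0.09 and the sex chromosome pair Ddx3x and Eif2s3 by 0.13, while acinar markers fell by 0.11 (all 21 below 0) and interferon response genes by 0.06. With an estimated correlation the adjusted p was 0.488 for blood markers, cholesterol synthesis, glycolysis and the sex chromosome pair and 0.767 for the others. Exact permutation of the list means called 0 lists, with a smallest p of 0.06, and adjusted over the list alone 0 members of any list passed. The mean and the test differed in sign for neutrophil and mast cell markers (mean 0.02, test and median downward), and the mean and the median for B cell markers (mean 0.02, median -0.02).

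The array female HFD-sired 1, with its intestine, brown fat and lymph node transcripts, moved several of these lists. Without it, fatty acid oxidation stood at -0.0070, oxidative phosphorylation at 0.03, T and NK cell markers at 0.05, endothelial markers at 0.03, mesenchyme at 0.03 and glycolysis at 0.02, all without a call, and the sex chromosome pair, at 0.11, also lost its call. Immediate early genes (0.19), cell cycle (0.14), cholesterol synthesis (0.07), blood (-0.24), acinar (-0.13) and interferon genes (-0.11) kept theirs, and 9 lists were called in all, with exocytosis (0.10) and neutrophil and mast cell genes (-0.05) turned in sign and ER stress genes at 0.08. Without both least correlated arrays 7 lists were called. The mean of interferon response genes changed sign without female control-sired 1, to 0.04, and in 9 further single-array omissions their call ended. Cell cycle (0.06) and cholesterol synthesis (0.06) lost theirs without male control-sired 4, and acinar markers stood at -0.0072 without male HFD-sired 1, with no call. Of 20 single-array omissions, 6 ended the call of acinar markers, 9 each those of endothelial and of T and NK cell markers, 7 each those of mesenchyme and of the sex chromosome pair, and 3 that of glycolysis.

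**Figure D3:**
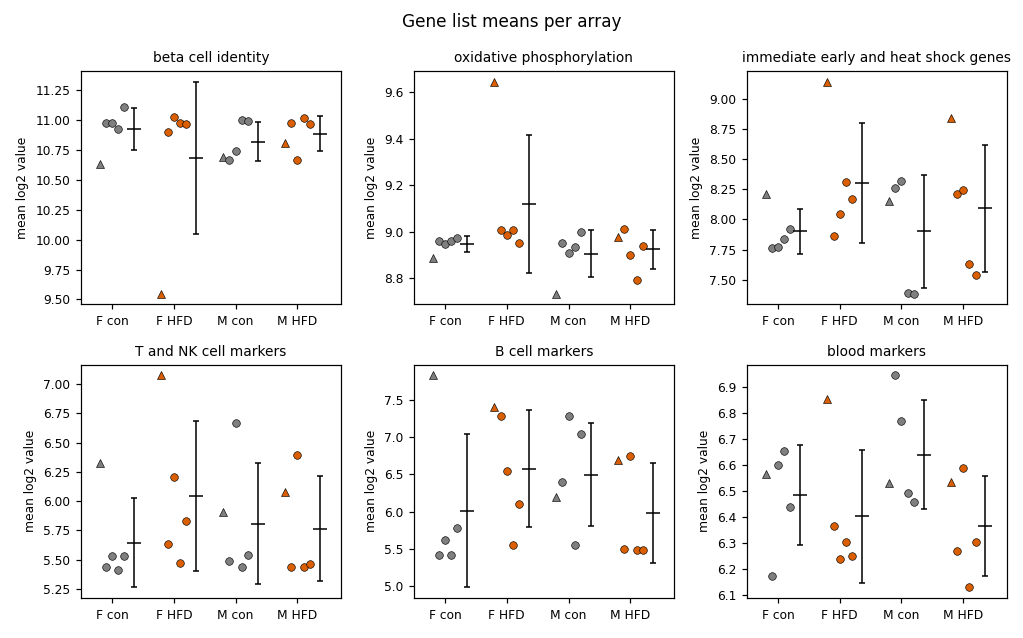
Mean log2 value of 6 gene lists in each array, for females (F) and males (M) sired by control (con) or HFD fathers; points are arrays, the triangle is replicate 1, and bars are mean ± SD of 5 arrays. Female HFD-sired 1 stands at 9.55 for beta cell identity and at 9.64 for oxidative phosphorylation, apart from every other array.

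In females, the largest increases with paternal HFD among single-symbol probe sets with an unadjusted p under 0.05 were in the stress and immediate early genes Atf3, higher by 1.11 ± 0.41 log2 (SE, 5 arrays against 5), and Fos, by 1.03 ± 0.37, followed by Klkb1, by 0.95 ± 0.18, a 1.93-fold difference. Egr1 was higher by 0.80 ± 0.28, Jun by 0.78 ± 0.31, Ppp1r15a by 0.61 ± 0.23, Ephx2, an epoxide hydrolase gene, by 0.59 ± 0.25 and Per1 by 0.53 ± 0.24. Decreases were largest in A1bg (-0.96 ± 0.36), Tnni3k (-0.64 ± 0.29), Itln1 (-0.63 ± 0.25), the 2 probe sets of the lipid flippase gene Atp11a (-0.61 ± 0.15 and -0.55 ± 0.15), the Wnt receptor gene Fzd6 (-0.55 ± 0.17) and the olfactory receptor genes Or5k15 (-0.52 ± 0.14), Or1o2 (-0.51 ± 0.22) and Or8b42 (-0.49 ± 0.12). None of these passed the adjusted threshold (adjusted p = 0.995). Reg3a and Reg3b are missing here because they did not reach the unadjusted threshold in females. Their lowest array was female HFD-sired 3 (6.01 for both), so their decrease cannot be placed in males alone. Ins1 (-0.03 ± 0.06), Ins2 (-0.01 ± 0.06), Iapp (-0.12 ± 0.22) and Il1b (0.13 ± 0.32) differed by less than their errors, and Tnf (0.12 ± 0.20) and Il13ra2 (0.78 ± 0.79) did as well. With limma 0 probe sets passed, and 797 had an unadjusted p under 0.05 (319 higher, 478 lower) against 1460.7 expected; least squares without moderation gave 0 and 913. Without female HFD-sired 1 the counts were 0 and 1082, and without female control-sired 1 the unadjusted count was 1306.

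Some immune cell lists were higher in HFD-sired females by camera at its preset correlation, and each of these calls was lost with an estimated correlation (adjusted p = 0.773). B cell markers rose by a mean of 0.56 log2, with all 12 members above 0 (Cr2 1.69 ± 1.21, Ms4a1 1.11 ± 0.85, Btla 0.93 ± 0.68, Cd79b 0.66 ± 0.46). T and NK cell markers rose by 0.40, all 20 members above 0 (Cd3g 1.45 ± 0.86, Il7r 0.67 ± 0.74, Cd3e 0.59 ± 0.35), macrophage and myeloid markers by 0.30, 19 of 23 (Ptprc 1.39 ± 0.99, Laptm5 0.76 ± 0.62, Lyz2 0.73 ± 0.80), and antigen presentation genes by 0.27, all 16 (RT1-Da 0.74 ± 0.74, Cd74 0.60 ± 0.68). The exact permutation p was 0.325, 0.254, 0.54 and 0.476 in that order. Lymph node structure markers were high in the same female HFD-sired 1, and without it the shifts were 0.35 for B cell, 0.14 for T and NK cell, -0.04 for macrophage and 0.05 for antigen presentation lists, none called. Of the 10 lists called without it, 4 were immune lists lower in HFD-sired females: interferon (-0.17), neutrophil and mast cell (-0.10), cytokine (-0.09) and JAK-STAT genes (-0.07). These too were lost with an estimated correlation (adjusted p = 0.737 for cytokine genes and 0.7 for the others), and without female control-sired 1 instead interferon stood at 0.12, cytokine at 0.27 and JAK-STAT genes at 0.19. The control-sired female 1 carried the highest B cell mean of the 20 arrays (7.83), and without it the B cell shift was 1.02. The macrophage call also ended without control-sired female 2 (0.13), 3 (0.23) or 4 (0.19). That of antigen presentation genes ended without control-sired female 2 (0.18) or 4 (0.17).

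Metabolic and beta cell lists moved with the same array, and their calls were lost with an estimated correlation (adjusted p = 0.773 for each). Oxidative phosphorylation genes rose by 0.17, all 31 members above 0 (Cycs 0.43 ± 0.26, Sdhb 0.35 ± 0.20, Sdha 0.32 ± 0.25), and fatty acid oxidation genes by 0.20, 20 of 21 (Ppargc1a 0.55 ± 0.40, Acaa2 0.44 ± 0.30, Acadm 0.37 ± 0.35). Immediate early and heat shock genes rose by 0.40 (16 of 18), cell cycle genes by 0.11 (26 of 28; Pcna 0.44 ± 0.12, Kif11 0.27 ± 0.18) and oxidative stress defence genes by 0.09 (16 of 19; Mt1 0.49 ± 0.44, Hmox1 0.30 ± 0.38). Beta cell identity genes fell by 0.24, all 17 below 0 (Ffar1 -0.46 ± 0.38, Isl1 -0.38 ± 0.35, Neurod1 -0.35 ± 0.33), and exocytosis and excitability genes by 0.20, 17 of 18 (Snap25 -0.35 ± 0.36, Chga -0.33 ± 0.32). No member passed when adjusted over the list alone (0 genes). The smallest exact permutation p of the 28 lists was 0.0317, for oxidative phosphorylation (adjusted p = 0.815). Without female HFD-sired 1, oxidative phosphorylation stood at 0.04, immediate early genes at 0.19 and cell cycle at 0.20, all still called at the preset correlation. With an estimated correlation these calls were lost in that fit as well (adjusted p = 0.7 for each). Fatty acid oxidation (-0.04), oxidative stress defence (-0.02), beta cell identity (0.04) and exocytosis (0.05) changed sign and lost their calls. Cell cycle genes stood at 0.04 without female control-sired 2, with no call. Mean and test differed in sign for duct (mean -0.03), mesenchyme (0.02) and neutrophil and mast cell markers (0.03).

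In males, Reg3b was lower with paternal HFD by a log2 difference of -2.37 ± 0.96 (SE, 5 arrays against 5) and Reg3a by -2.28 ± 0.92. Adora1 (-0.59 ± 0.11) and the glucuronosyltransferase gene Ugt2b37 (-0.73 ± 0.15) had the smallest errors relative to their size among the large decreases, followed by Or4k42b (-0.83 ± 0.21), Fgl1 (-0.60 ± 0.17), Itih4 (-0.56 ± 0.18), the chemokine receptor gene Ccr6 (-0.70 ± 0.26), the complement factor gene Cfi (-0.56 ± 0.23) and Hbb-b1 (-0.69 ± 0.32). Among single-symbol probe sets past the unadjusted threshold, increases were largest in Plcxd3 (0.59 ± 0.21), S100a11 (0.55 ± 0.24), Tmprss3 (0.51 ± 0.22), Thy1 (0.51 ± 0.15), the growth factor gene Tgfb2 (0.50 ± 0.16), Lingo2 (0.48 ± 0.14) and Lactb2 (0.45 ± 0.20). The adjusted p was 0.838 for all of them. Ins1 (-0.05 ± 0.08), Ins2 (-0.04 ± 0.08), Il1b (0.06 ± 0.21), Ccl2 (0.06 ± 0.40) and Il13ra2 (0.20 ± 0.75) differed by less than their errors, and Tnf was at -0.19 ± 0.18. With limma 0 probe sets passed, and 1093 had an unadjusted p under 0.05 (431 higher, 662 lower) against 1460.7 expected; least squares gave 0 and 1212. Leaving out male HFD-sired 2 gave 1 adjusted call. Without male control-sired 1 the counts were 0 and 1022, and without male control-sired 3 the unadjusted count was 1911.

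Camera called 7 lists in males, and none with an estimated correlation. B cell markers fell by 0.51 log2, all 12 members below 0 (Cr2 -1.64 ± 1.02, Ms4a1 -0.65 ± 0.55), blood markers by 0.27, 7 of 8 (Hbb -0.60 ± 0.28, Alas2 -0.39 ± 0.18), antigen presentation genes by 0.18, all 16 (Cd74 -0.42 ± 0.57, Ciita -0.34 ± 0.18), and acinar markers by 0.15, all 21 (Ptf1a -0.37 ± 0.32, Cuzd1 -0.33 ± 0.29). Mesenchyme genes rose by 0.21, 18 of 19 (Thy1 0.51 ± 0.15, Rgs5 0.37 ± 0.11), endothelial markers by 0.19, 12 of 13 (Cdh5 0.40 ± 0.20, Pecam1 0.28 ± 0.18), and exocytosis genes by 0.14, 17 of 18 (Snap25 0.37 ± 0.20, Syt4 0.27 ± 0.19). The adjusted p with an estimated correlation was 0.832 for 6 of these lists and 0.843 for acinar markers, and 0 members passed when adjusted over the list alone. B cell markers followed the lymph node structure markers over the male arrays (r 0.75 within groups; permutation p = 0.00049 over all 20 arrays, r 0.77). The smallest exact permutation p was 0.0794, for blood markers. The acinar mean was lowest in male HFD-sired 1 (11.67), and without that array the acinar shift changed sign, to 0.05. Mesenchyme (0.05) and endothelial markers (0.11) had no call in that fit. The exocytosis call ended without male HFD-sired 4 (0.10). Antigen presentation stood at -0.05 without male control-sired 3, where lymph node markers were high, also with no call. Mean and test differed in sign for neutrophil and mast cell (mean 0.01), oxidative stress (-0.03) and cytokine genes (0.03).

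The difference between the sexes in the response to paternal diet, female effect minus male effect, was largest among single-symbol probe sets with an unadjusted p under 0.05 for Kmo, a kynurenine pathway enzyme gene (1.30 ± 0.57 SE, 20 arrays), Acap1 (1.203 ± 0.52), the calcium channel gene Trpv6 (1.07 ± 0.51), Bmp2 (0.92 ± 0.38) and Xkrx (0.78 ± 0.31), and in the other direction for Thy1 (-0.85 ± 0.28), Slitrk6 (-0.84 ± 0.35), the glutathione peroxidase gene Gpx3 (-0.80 ± 0.32), Sorbs2 (-0.73 ± 0.24) and Fzd6 (-0.73 ± 0.28). All had an adjusted p of 0.922. For the inflammation genes it was 0.07 ± 0.40 for Il1b, 0.31 ± 0.28 for Tnf, -0.01 ± 0.72 for Ccl2 and 0.59 ± 1.18 for Il13ra2. With limma 0 probe sets passed, and 950 had an unadjusted p under 0.05 (441 higher, 509 lower); least squares gave 0 and 1076, and the counts without both least correlated arrays were 0 and 1046. In simulated arrays with independent probe sets, 61% of interactions of 1 log2 and 13% of those of 0.5 were recovered, which has the same limit.

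Immune lists made up 3 of the 9 list calls for this interaction. B cell markers differed by 1.08 log2, all 12 members above 0 (Cr2 3.33 ± 1.70, Ms4a1 1.76 ± 1.08), antigen presentation genes by 0.45, all 16, and T and NK cell markers by 0.44, 19 of 20 (Cd3g 1.31 ± 1.30, Cd6 0.58 ± 0.27). All 3 calls were lost with an estimated correlation (adjusted p = 0.882). These 3 were called whichever array was left out, between 0.87 and 1.53, 0.23 and 0.71, and 0.19 and 0.61, but with genes above the median level alone T and NK cell markers stood at -0.0077. Over the 20 arrays, lymph node structure markers followed the B cell (r 0.77, permutation p = 0.00049) and T and NK cell lists (r 0.99, permutation p = 1e-05, the smallest possible). Some of these markers are themselves immune genes, so such relations may be partly built in. Oxidative phosphorylation (0.15) and fatty acid oxidation genes (0.17) were relatively higher in females, and beta cell identity (-0.31), exocytosis (-0.34), endothelial (-0.20) and mesenchyme genes (-0.19) relatively lower. The adjusted p with an estimated correlation was 0.882 for all 9, and 0 members passed when adjusted over the list alone. Without female HFD-sired 1 the values were 0.87 for B cell, 0.23 for antigen presentation and 0.19 for T and NK cell markers, all called. Oxidative phosphorylation (0.02), beta cell identity (-0.02) and exocytosis (-0.08) were not called in that fit, and fatty acid oxidation changed sign, to -0.08. Endothelial and mesenchyme calls each ended in 10 of 20 single-array omissions. The smallest exact permutation p was 0.0126, for sex hormone, prolactin and growth hormone signalling genes (mean -0.13), with an adjusted p of 0.352. Signs differed for duct markers (mean -0.01, test and median upward), and between mean and median for neutrophil and mast cell markers (0.02, -0.01) and glycolysis genes (0.05, -0.04).

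Diet effects in females and males showed no detectable relation across probe sets: Pearson's r was -0.048 and Spearman's rho -0.034 across 29214 probe sets, which are not independent replicates, and 84 of 100 relabellings gave a correlation as far from 0 (permutation p = 0.842). Among probe sets with an unadjusted p under 0.05 in both sexes, 7 were higher in both, against 4.71 expected by chance, 18 lower in both, against 10.8 expected, and 11 differed in opposite directions. All 36 compare with 29.8 expected, and no test was made of the excess in the same direction. Of 9 named genes lower in both sexes, 5 were dim olfactory receptor genes (Or51q1d, Or51q1e, Or13a26c, Or5k3 and Or11j4), and the others were Adora1 (-0.45 in females, -0.59 in males), Itih4 (-0.30 and -0.56), the calcium channel subunit gene Cacng6 (-0.28 and -0.22) and Msx2 (-0.20 and -0.36), and Lactb2 was higher in both (0.23 and 0.45); these were chosen after their values were seen.

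Between the sexes, 3 probe sets passed the adjusted threshold. Actc1, the cardiac actin gene, was lower in females, with a log2 difference of -0.51 ± 0.07 (SE, 10 arrays against 10, adjusted p = 0.00726). Females lay between 6.08 and 6.50 and males between 6.61 and 7.08, so all 10 male arrays were above every female array. The unnamed probe sets 10934517 and 10936669 were higher in females by 0.77 ± 0.10 and 0.56 ± 0.07 (adjusted p = 0.00315 for both), and 10 of 10 female arrays lay above every male for the second. These 3 were chosen by passing the threshold, outside the rule for named genes. X-linked genes that escape silencing were higher in females, Eif2s3 by 0.49 ± 0.10 and Ddx3x by 0.21 ± 0.06, and both passed when adjusted over the list alone, though not over all probe sets (adjusted p = 0.366 and 0.816). Xist and the Y-linked Kdm5d were not named on the array here.

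**Figure D4:**
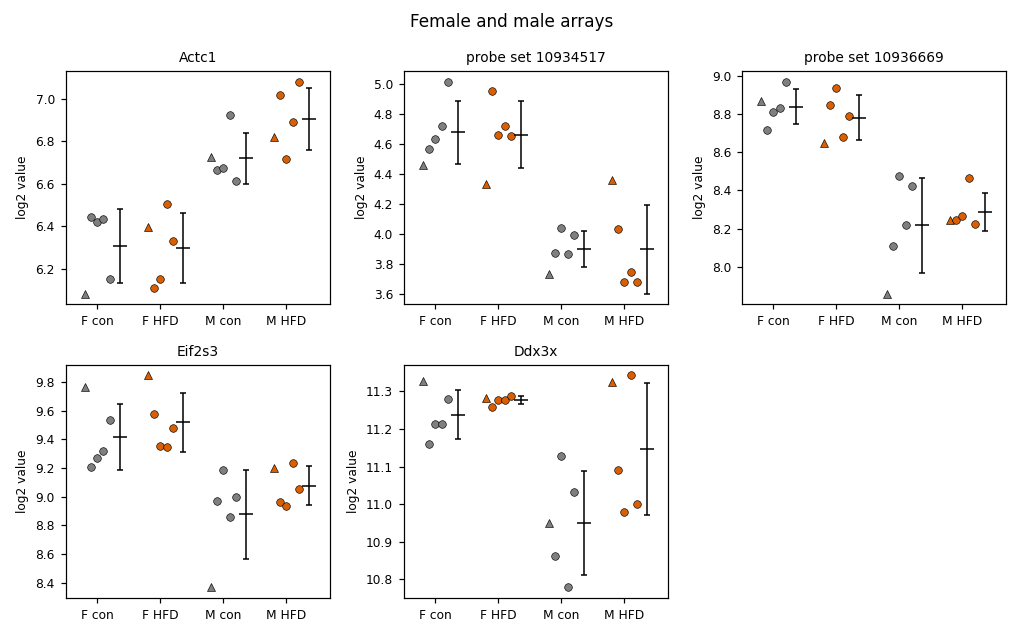
Log2 values of Actc1, 2 unnamed probe sets, Eif2s3 and Ddx3x in each array, for females (F) and males (M) sired by control (con) or HFD fathers; points are arrays, the triangle is replicate 1, and bars are mean ± SD of 5 arrays. All 10 male arrays lie above every female array for Actc1.

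Further genes with large sex differences came from several cell types: the duct markers Tspan8 (1.03 ± 0.35) and Krt19 (0.57 ± 0.26) were higher in females, along with Cxcl6 (0.80 ± 0.38), Dpt (0.54 ± 0.26) and Ifi44l (0.48 ± 0.20), while the acinar genes Cuzd1 (-0.98 ± 0.29), Rbpjl (-0.84 ± 0.26) and Spink1 (-0.73 ± 0.34) were lower, along with Slc25a35 (-0.82 ± 0.23) and the metallothionein gene Mt1 (-0.72 ± 0.33). None passed the adjusted threshold. With limma 1606 probe sets had an unadjusted p under 0.05 (619 higher in females, 987 lower). Camera called 13 lists at its preset correlation, 12 up in females and acinar markers down (-0.18, 20 of 21 members). The sex chromosome pair (0.35) was the single list called with an estimated correlation (adjusted p = 0.0214) and by permutation (permutation p = 3.15e-05, the smallest that the splits allow). Interferon response genes (0.17, 27 of 29; Ifit1 0.54 ± 0.33, Ifit2 0.38 ± 0.14) and oxidative phosphorylation genes (0.12, 30 of 31) had an adjusted p of 0.625 with an estimated correlation, as had fatty acid oxidation (0.16) and duct markers (0.20). That p was 0.417 for glycolysis (0.07) and 0.686 for acinar, macrophage (0.27), antigen presentation (0.15), cytokine (0.12), mesenchyme (0.14), immediate early (0.11) and JAK-STAT genes (0.08). Without female HFD-sired 1, 5 lists were called, and macrophage (0.10), cytokine (0.01), antigen presentation (0.04), mesenchyme (0.05), fatty acid oxidation (0.04), duct (0.12), glycolysis (0.03), JAK-STAT (0.0069) and immediate early genes (0.0020) were not, while beta cell identity genes turned to 0.09 and were called. Without female control-sired 1, 6 lists were called, and interferon response genes fell to 0.08 but kept their call. The acinar call ended without female control-sired 5 (-0.10) or female HFD-sired 3 (-0.11). Signs differed for oxidative stress genes (mean -0.01, test and median upward) and, between mean and median, for endothelial markers (0.0016, -0.01).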

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

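The test on female HFD-sired 1 alone for intestine markers, those on the T and NK cell shift without that array, on the B cell permutation p and on Reg3a were chosen after the results had been seen, and the limit for excluding paternal diet in the B cell test was revised then. So were chosen the intestine excess over a fitted line, the relation without B cell genes and the Reg3a fits without female HFD-sired 5. The tests on both arrays, brown fat, signal slope, paternal diet and lymph node markers, and the counts of other splits, were set before their values were seen.

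Of 168 sets of 5 values tested (28 list means, 2 array measures and 12 genes in 4 groups), 32 held an array far from the rest by its gap to the nearest other array, where chance flags about 1 in 20, or 8.4. Female HFD-sired 1 accounted for 14. Its mean log2 value was 9.55 for beta cell identity, 7.98 for alpha, delta and PP cell markers, 7.49 for exocytosis and 9.23 for ER stress genes, all below the other HFD-sired females. It was above them at 9.24 for mesenchyme, 7.29 for cytokine, 7.68 for apoptosis, 9.64 for oxidative phosphorylation, 9.33 for fatty acid oxidation, 8.88 for glycolysis and 6.85 for blood genes. Gcg stood at 13.15, Iapp at 12.08 and its median correlation at 0.941.

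Female control-sired 1 was above its group at 6.32 for T and NK cell markers, 7.83 for B cell markers, 7.03 for interferon, 7.46 for apoptosis genes and 6.06 for Cd3e, and below it at 11.58 for Slc2a2, 13.66 for Gcg and 0.977 for its median correlation. Male control-sired 3 was high at 8.79 for mesenchyme, 7.87 for macrophage markers, 8.18 for JAK-STAT genes, 6.52 for Il1b and 7.05 for Il13ra2. Acinar means were low in female control-sired 5 (11.74) and male HFD-sired 1 (11.67). Male control-sired 1 had a median correlation of 0.963, male control-sired 5 a mean of 6.89 for sex hormone and growth hormone genes, and Ins2 stood at 13.93 in female HFD-sired 2.

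The diet effect differed between females and males, by camera's interaction test at the preset correlation, in 9 lists. Female effect minus male effect was 1.08 for B cell, 0.44 for T and NK cell, 0.45 for antigen presentation, 0.15 for oxidative phosphorylation, 0.17 for fatty acid oxidation, -0.31 for beta cell identity, -0.34 for exocytosis, -0.20 for endothelial and -0.19 for mesenchyme genes. No list was called here with an estimated correlation. Of 100 splits of the arrays, 70 gave as many list calls, with up to 22 in another split, so chance cannot be excluded.

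The low correlation of female HFD-sired 1 and male control-sired 1 with the rest may come from RNA of other tissues, from compressed signal or, for the female, from paternal diet. Small intestine markers not inspected before lay 2.79 log2 higher in female HFD-sired 1, as intestinal RNA there would give. Brown fat markers had a median 0.74 higher, short of the 1 log2 set in advance, so brown fat stays open by that limit, although 7 of the 14 genes exceeded it. Whether these came from brown fat or from other fat was not tested. Paternal diet is argued against by the limit set in advance. The other 4 HFD-sired females minus the control-sired females gave 0.061 as the larger, with sign, of the 2 median differences. Of the 12 intestine genes seen beforehand, however, 8 were more than 1 higher in female HFD-sired 5, and all 12 in male control-sired 1. In male control-sired 1 the lower excess of intestine markers (0.83, also short of 1) and a slope of 0.904 on the median array, below the lowest of the 18 others (0.977), leave intestinal RNA and compressed signal open as causes of its low correlation. Linear compression alone does not account for the intestine excess, which was 0.67 above the straight line of that array on the median array. There 12 of 13 genes lay above the line, as in male control-sired 4, where the median excess was 0.11. The 6 brighter markers of male control-sired 1 had an excess of 0.42 over the line and 0.23 before it. Compression toward the array median (6.49), even if stronger among dim probe sets, would not carry values past it or raise those above it. Guca2a read 7.26 there against a median of 5.72 in 18 other arrays. Guca2b (8.28 against 7.16) and Tff3 (7.60 against 6.77) also rose, while Olfm4 and Enpep fell. For Guca2a, Guca2b and Tff3 these values argue against compression alone. For the other markers compression that is stronger among dim probe sets was not tested and stays open.

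B cell, T and NK cell, macrophage and antigen presentation lists were higher with paternal diet in females by camera's preset correlation, calls lost with an estimated one (adjusted p = 0.773). Without female HFD-sired 1, 35.4% of the T and NK cell shift was left, so that array carried most of it. Leaving out female control-sired 1 instead, where these markers were also high (6.32), raised the shift to 0.57. B cell markers rose and fell with uninspected lymph node structure markers over the 20 arrays, with group means removed (Pearson r 0.77, permutation p = 0.00049; Spearman rho 0.78, permutation p = 0.00022). Adjusted over 5 relations, these permutation p were 0.00049 and 0.000275. Without the 2 arrays with the most extreme lymph node values the r was 0.75, for which no p was computed. Without B cell genes and Marco among the markers, r was 0.67 (permutation p = 0.0023) and rho 0.68 (permutation p = 0.00261). That r was 0.61 without the same 2 arrays. Varying amounts of lymphoid tissue among the islets could give such relations. Paternal diet cannot be told apart from this: the B cell difference had an exact permutation p of 0.325, with a 95% interval from -0.77 to 1.90, and lymphoid tissue in or near islets could itself vary with diet.

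Reg3a was lower in HFD-sired offspring by -2.24 log2 without passing the adjusted threshold. With the acinar marker score as covariate the difference was -1.98 and without the 2 least correlated arrays -2.12, so neither this linear adjustment nor leaving out those 2 arrays removed most of it. Female HFD-sired 5, where intestine genes seen beforehand were 1.40 higher, was kept in that test, and leaving it out alone or with them gave -2.51 and -2.45. Acinar genes read high on the scale (list means 12.41 and 12.52), where a linear covariate may correct too little. The lowest Reg3a arrays of the 2 diets, female HFD-sired 3 (6.01) and female control-sired 5 (10.05), shared an acinar mean of 11.74. Besides female HFD-sired 3, only male HFD-sired 1 (11.67) of the HFD-sired arrays had an acinar mean under 12.32. Yet 6 of 10 HFD-sired arrays lay below every control in Reg3a. These values argue against less acinar tissue, as this list measures it, as the main cause. A smaller contribution stays open. Chance among 29214 probe sets and the sharing of fathers by some arrays stay open, and paternal diet is a hypothesis that these arrays leave untested beyond that.

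Other splits of the arrays bear on the counts. For probe sets at an unadjusted p under 0.05, 48 of 100 splits gave at least the 1151 of both sexes (highest other 3534), 55 the 797 in females (4241), 44 the 1093 in males (4504), 54 the 950 of the interaction (4707) and 26 the 1606 between the sexes (3921). Splits with several times the real count point to a structure of the arrays that follows neither diet nor sex. For lists called by camera, 54 of 100 gave at least 13 across both sexes (highest other 22), 67 at least 11 in females (23), 75 at least 7 in males (17) and 51 at least 13 between the sexes (24). Chance can be excluded for none of these counts. The count of 3 probe sets called between the sexes was reached by 1 of 100 splits, the real one, with 0 in every other. Chance is thus unlikely for that count, as far as 100 splits can show, and no single probe set was tested in this way.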

How the results depend on the processing

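The fits without both least correlated arrays, those for Reg3a without female HFD-sired 5, the Reg spreads without the farthest array, the lymph node markers without B cell genes, the intestine excess over a fitted line and the estimated correlation without female HFD-sired 1 were chosen after the results had been seen, and the other alternatives before. No paired analysis was possible because no pairing of animals is given. There were 338 gene results, of which 3 were called, and 140 list results. No gene result changed its label, which says little where hardly any was called. Single-symbol probe sets alone, or those above the median level, mostly lower counts because fewer are tested; why other results moved was not tested.

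Probe sets above the median level gave 478 unadjusted calls across both sexes, 241 in females, 620 in males, 511 for the interaction and 911 between the sexes, with 8, 4 and 4 lists across both sexes, in males and between the sexes, and -0.0077 for T and NK cell markers in the interaction. Single-symbol probe sets gave 486, 307, 513, 445 and 848, with 1 adjusted call between the sexes. Array weights gave 2039 across both sexes, 1862 in females and 2516 between the sexes, 5 adjusted calls between the sexes, 4 lists across both sexes and 2 between the sexes, where antigen presentation stood at -0.0047 and JAK-STAT genes at -0.00013. Quantile normalization gave 5 lists across both sexes, and the acinar covariate 0.0027 for oxidative stress genes between the sexes. A threshold of 0.1 and the additive model each gave 5 calls between the sexes, and a single fit of all arrays 1845 unadjusted calls in males. Estimated correlation, fry and permutation of list means each called 0 lists for diet and the interaction and 1 between the sexes. Within a sex the permutation count of 0 was nearly fixed by its smallest p of 0.00794.

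Without both least correlated arrays 7 lists were called across both sexes and 4 between the sexes, with 5 adjusted probe sets between the sexes. Exocytosis (0.082), antigen presentation (-0.074) and fatty acid oxidation (-0.033) changed sign across both sexes, beta cell identity (0.0077) and fatty acid oxidation (-0.023) in the interaction, and beta cell identity (0.078) and JAK-STAT genes (-0.013) between the sexes.

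Leaving out 1 array at a time, 19 counts moved and 221 stayed the same, 21 list results changed sign, 142 were weaker, 116 stronger and 1961 the same; the 5460 gene results kept their labels, nearly all of them without a call. Called lists ranged from 4 to 20 across both sexes, 7 to 16 in females, 6 to 12 in males, 7 to 11 for the interaction and 5 to 15 between the sexes. Unadjusted calls ranged from 817 to 2040, 643 to 1306, 677 to 1911, 688 to 1408 and 1310 to 2308 in that order. Adjusted calls ranged from 0 to 1 in males and 3 to 5 between the sexes and stayed at 0 elsewhere, and the relation of the sexes from -0.14 to 0.11. In females the ranges were -0.23 to 0.090 for acinar, -0.32 to 0.044 for beta cell identity, -0.095 to 0.27 for cytokine, -0.29 to 0.053 for exocytosis, -0.045 to 0.29 for fatty acid oxidation, -0.17 to 0.12 for interferon, -0.068 to 0.19 for JAK-STAT, -0.041 to 0.64 for macrophage, -0.16 to 0.16 for mesenchyme, -0.10 to 0.098 for neutrophil and mast cell and -0.024 to 0.15 for oxidative stress genes. They were -0.24 to 0.048 for acinar markers in males. Across both sexes they were -0.075 to 0.095 for exocytosis, -0.0070 to 0.16 for fatty acid oxidation, -0.11 to 0.040 for interferon and -0.048 to 0.053 for neutrophil and mast cell genes. For the interaction they were -0.075 to 0.26 for fatty acid oxidation and -0.13 to 0.17 for interferon genes, and between the sexes -0.091 to 0.094 for beta cell identity and -0.068 to 0.021 for oxidative stress genes. For the list means most of these extremes came without female HFD-sired 1 or female control-sired 1, while those of the counts were spread over many arrays.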

Other observations

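The correlations and counts in this part, and the choice of Reg1a, Reg3g, Reg4 and the olfactory receptors, came after the results had been seen.

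Il13ra2, a decoy receptor of interleukin 13, ranged from 3.29 to 7.64 between arrays and followed lymphoid transcripts within the groups, a relation that leaves a difference by paternal diet open. With group means removed, its level rose with lymph node structure markers over the 20 arrays (Pearson r 0.92, permutation p = 2e-05; Spearman rho 0.84, permutation p = 4e-05; adjusted over 5 relations 5e-05 and 6.67e-05). The r was 0.86 without female HFD-sired 1 and male control-sired 3, the arrays with the most extreme lymph node values, 0.90 among females and 0.94 among males. T and NK cell markers followed the same axis most closely (r 0.99, permutation p = 1e-05, the smallest that the resamples allow; rho 0.92, p = 2e-05), as did cytokine and NF-kB genes (r 0.94, permutation p = 3e-05; rho 0.88, p = 1e-05) and macrophage markers without Marco (r 0.92, permutation p = 0.00012; rho 0.75, p = 0.00046). Without B cell genes and Marco among the markers, r for T and NK cell markers was 0.97. The remaining markers still include immune genes such as the chemokine genes Ccl19 and Ccl21, so relations with immune lists may be partly built in. The arrays above 5 in Il13ra2 came from all groups: female HFD-sired 1 (7.64), male control-sired 3 (7.05), male HFD-sired 3 (6.28), male HFD-sired 1 (6.16), female control-sired 1 (5.82), female HFD-sired 3 (5.63) and female control-sired 5 (5.32). The last of these went against the relation, with lymph node markers at -0.09.

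The spread of several Reg genes differed by paternal diet, without a test of variances. The SD over 10 arrays was 2.23 in HFD-sired against 0.95 in control-sired animals for Reg3a, 2.41 against 1.13 for Reg3b, and 0.40 against 0.16 for Reg1a. Without the farthest array of each diet these were 1.99 against 0.80, 2.10 against 0.95 and 0.31 against 0.10. A wider spread in HFD-sired arrays was not particular to Reg genes: the SD was 0.28 against 0.14 for Adora1 and 0.60 against 0.42 for Klkb1. Control-sired Reg1a reached 13.56, near the top of the scale (14.17), where a spread between arrays is hard to see. For Reg4 (1.06 against 0.50) and Reg3g (1.63 against 1.81) the direction rested on single arrays: without the farthest, female HFD-sired 1 and male control-sired 1 for Reg4 and female HFD-sired 5 and male control-sired 1 for Reg3g, it turned, to 0.20 against 0.25 and 1.45 against 1.03. Reg1a, an abundant secreted protein gene of acinar cells, was at 13.04 in HFD-sired and 13.40 in control-sired animals (log2 difference -0.36 ± 0.13, adjusted p = 0.962), with 5 of 10 HFD-sired arrays below every control. Reg3g (-0.33 ± 0.69) and Reg4 (0.21 ± 0.34) were not past the threshold either. Olfactory receptor genes, dim at a mean near 4, made up 42 of the probe sets lower across both sexes at the unadjusted threshold, 3.93% of the 1069 measured against 1.90% of other named probe sets. Their mean differed by -0.05 log2 between diets (exact permutation p = 0.4), and it was highest in male control-sired 1 (4.39).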
